A study of Bos taurus with 40 samples.

How the data were processed

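Total RNA from biceps brachii of 40 calves was hybridized by the authors to one-colour (cyanine 3) Agilent Bos taurus oligonucleotide arrays, 1 array per animal, 10 from controls and 30 from treated calves. Per the labels, the treated groups received prednisolone (15 mg per animal per day by mouth for 31 days, 8 calves), brotizolam (0.02 mg/kg by mouth for 31 days, 8 calves) or dexamethasone (0.4 mg per animal per day by mouth for 31 days, 6 calves), or ractopamine (80 mg per animal per day by mouth for 31 days) with nandrosol (150 mg per animal every 2 weeks, 4 times; 8 calves). The brotizolam and dexamethasone groups also received estradiol (5 mg per animal intramuscularly each week, 6 times). Groups were taken from the labels, which name the group of each sample; no sample was left out. The labels name no sex, age, breed or farm, and a difference between groups in any of these would enter each comparison with control.

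Per the file headers, the authors read spot intensity with Feature Extraction 9.5.1.1 from a pair of scans per slide at 5 micron, and the processed signal is an intensity after background subtraction and multiplicative detrending within the array, with no step between arrays. The deposited mean spot signal and median local background are intensities without correction. Other deposited columns are flags of 0 or 1 per spot (other than intensity) for found, well above background, saturated and outlier spots. The deposited value table holds linear intensities that the authors made with R 2.11.1 by a normalization between arrays that is not stated; its rank correlation with the processed signal was at least 0.961 on every array, its column medians ran from 76.1 to 218.6, and 91.8% of its 311717 empty cells were spots that had not been found. That table served as an alternative only.

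Each array had 44407 features, of which 42990 were not controls and measured 21475 probes, 21465 of them with 2 spots and 10 with 6. Log2 processed signals were averaged over a probe's spots without spots marked as outliers (2 to 82 per array), and each array's 75th percentile was subtracted. A probe was tested when it was well above background on at least 6 of the 40 arrays, the size of the smallest group, which left 16110 probes (75.0%) and 11718 gene symbols; 3 values were missing. Gene names came from the array annotation and a table of cattle genes (assembly ARS-UCD2.0), matched in turn by accession (3504 probes), gene number (9610), symbol (297), synonym (86) or description (2721), which named 16218 probes with 14618 symbols and left 5257 unnamed. A gene with several probes is represented by the probe with the highest mean over all arrays.

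Signal levels differed between groups. The 75th percentile of the processed signal was 535.2 to 1006 on control arrays, 665.8 to 1700 with prednisolone, 872.7 to 1385 with brotizolam and estradiol, 871.5 to 1509 with dexamethasone and estradiol and 433.0 to 843.6 with ractopamine and nandrosol, and the lowest share of probes above background (48.1%) was on ractopamine replicate 36. Where a gene was above background on no array of 1 group, its fold is given as a bound ("at least") against the background level. No pair of arrays held identical values (highest correlation 0.989).

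A single linear model of the 5 groups was fitted per probe with limma 3.58.1 (R 4.3.3, lmFit and eBayes). Contrasts were each treatment minus control, dexamethasone with estradiol minus prednisolone and minus brotizolam with estradiol, and a moderated F-test over the 4 treatments. The threshold was a Benjamini-Hochberg adjusted p of 0.05 over the tested probes of a comparison, two-sided. The 36 gene lists, written from general knowledge of muscle, the drugs' receptors and other cell types, were tested with limma's camera with its preset correlation of 0.01, adjusted over 36 lists and 4 comparisons (144 tests), beside an estimated correlation between genes and fry, which tests whether a list's genes move on balance one way and does not compare them with other genes. The lists covered glucocorticoid targets, atrophy and autophagy, proteasome, ribosomal proteins, myogenesis, slow and fast fibres, oxidative phosphorylation, citric acid cycle, glycolysis, fatty acid oxidation, lipid and cholesterol synthesis, extracellular matrix, markers of fibroblasts, adipocytes, endothelium, smooth muscle and pericytes, macrophages, lymphocytes, Schwann cells and erythroid cells, antigen presentation, interferon response, cytokines, denervation, beta-adrenergic and cAMP genes, androgen and polyamine genes, estrogen response, the growth hormone and insulin-like growth factor axis, the circadian clock, heat shock and unfolded protein genes, immediate early genes, hypoxia, antioxidants and metallothioneins, and the cell cycle. A count "adjusted over the list alone" uses only the list's genes.

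Slides and scan days were read from the file headers, which show 10 slides of 4 arrays and 4 scan days. Slides 1 to 4 and 5 to 10 formed 2 sets that separated on the first principal component. Each comparison was refitted with slide set and with scan day as a fixed term and recomputed within each set and day that held both groups, and the slide set term was chosen after the data were seen. The brotizolam group shared no scan day with a control. Overlaps of calls, whose comparisons share the 10 controls, were set beside 20 simulations of unchanged groups, the product expected of independent lists, and 20 splits of the controls into 5 and 5.

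The genes named in the text follow a rule. For each treatment against control it takes the 8 genes that rose and the 8 that fell with the largest change among those past the threshold, up to 4 members with the smallest p of each list that passed camera or had at least 3 members past the threshold, and FKBP5, TSC22D3, KLF9, PDK4, FBXO32, TRIM63, MSTN, IGF1, OXT, NR3C1, ESR1, MYH1 and MYH7 whatever their result (the results of 2 further genes of this part are not reported here). Where fewer than 5 genes passed it would have taken the 5 with the smallest p. For comparisons between treatments and the F-test it takes the 5 largest rises and falls. The text names the first and last of these parts in full and the list members in part. GREB1 with prednisolone and ractopamine and between treatments was chosen after its values were seen. The groups, contrasts, filter, threshold, lists, naming rule and alternatives, except the terms for slide set and the scan day term for lists, were fixed before the data were examined.

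Alternatives, changed 1 at a time, were quantile normalization, the array median for scaling, normexp background correction (offset 50) of the mean signal, the authors' value table, no filter on dim probes, a filter at 20 arrays, eBayes with trend and robust settings, array weights (0.381 to 1.88), slide as a random block (consensus correlation 0.144) or as a fixed term, scan day as a fixed term, only the compared groups in the fit, and leaving out each array in turn; for lists also the mean over a gene's probes. Other splits of the arrays into groups of the same sizes were counted, up to 100 per comparison.

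The pipeline was tested on simulated data with 200 changed probes per comparison. Without a slide set effect it recovered 70.1% to 80.6% of changes of 1 on the log2 scale in the comparisons with control (25.4% to 35.8% of changes of 0.5) and called 4 to 8 unchanged probes. With a simulated slide set effect (SD 0.5) the fit of groups only called 4417 unchanged probes for prednisolone, 4529 for brotizolam, 1647 for dexamethasone and 2 for ractopamine. The fit with slide set called 9, 9, 4 and 5. With prednisolone it recovered 53.7% of the changes of 1 and 3.0% of those of 0.5, against 77.6% and 49.3% with groups only.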

Results

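Transcript levels were measured in biceps brachii muscle of 40 calves, 1 array per animal, to find which transcripts differ between calves given growth promoters and controls. The groups were 10 controls, 8 calves given the glucocorticoid prednisolone, 8 given brotizolam (a sedative acting on benzodiazepine receptors) with estradiol, 6 given the glucocorticoid dexamethasone with estradiol, and 8 given ractopamine (a beta-adrenergic agonist) with nandrosol (an anabolic steroid preparation). Values after a gene are log2 fold changes ± SE, treated minus control, from 1 limma model of all 40 arrays, with p adjusted over 16110 probes. "Rose" and "fell" are used only where the adjusted p was under 0.05. Between 48.1% and 74.9% of the probes on an array were well above background, and control arrays (52.3% to 71.0%) and ractopamine arrays (48.1% to 67.8%) lay lower than prednisolone arrays (64.9% to 74.3%).

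The arrays fell into 2 sets of slides that were unevenly shared between the groups. Set 1 (16 arrays) held 8 controls, 7 ractopamine arrays and 1 dexamethasone array, and set 2 (24 arrays) held 2 controls, all prednisolone and brotizolam arrays, 5 dexamethasone arrays and 1 ractopamine array. The first principal component carried 19.5% of the variance, and 88.6% of its spread lay between the slide sets against 70.6% between the 5 groups. The sets were chosen after the data were seen, which favours their share. Between the scan days, read from the headers, lay 74.0%. The count of calls in each comparison is therefore given with slide set as a term, with scan day as a term and within batches that held both groups, beside the fit of groups only. Ractopamine with nandrosol was spread over both sets like the controls, whereas prednisolone and brotizolam with estradiol could be compared within a set with 2 controls only.

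**Figure D1:**
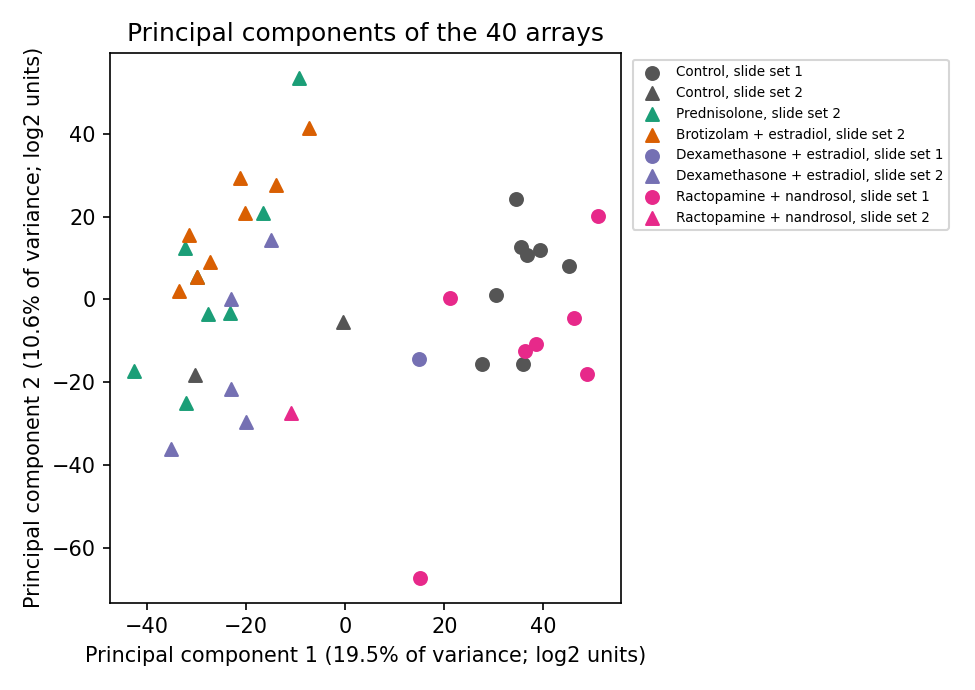
Each point is 1 of the 40 arrays, placed by its scores on the first and second principal components (19.5% and 10.6% of the variance, log2 units), coloured by group and shaped by slide set. All 16 arrays of slide set 1 lie outside the range of the 24 arrays of slide set 2 on the first component.

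With ractopamine and nandrosol, genes of the blood vessel wall were lower than in control muscle. SOX18, a transcription factor of endothelial cells, was 3.01-fold lower (-1.59 ± 0.15, adjusted p = 1.9e-08, n = 8 and 10), and ENG, an endothelial co-receptor for TGF-beta ligands, was 2.02-fold lower (-1.02 ± 0.12, adjusted p = 7.9e-07). The adhesion molecule ESAM (-0.78 ± 0.12) and the secreted vessel factor EGFL7 (-0.60 ± 0.11) fell as well, each below the control mean in 8 of 8 treated arrays. Of 16 endothelial markers tested, 12 fell and 0 rose (list median -0.60, camera adjusted p = 5.0e-18), the same count when adjusted over the list alone. This was the only list call in any comparison that held with an estimated correlation between genes (adjusted p = 0.022). The list median was -0.61 within slide set 1 (7 treated and 8 control arrays), -0.78 within set 2 (1 and 2), and -0.64, -0.53 and -0.68 within the 3 scan days that held both groups. SOX18 itself gave -1.61 and -1.47 within the sets. Genes of smooth muscle and pericytes, which wrap vessels, also fell: the signalling regulator RGS5 (-0.74 ± 0.12), the adhesion molecule MCAM (-1.04 ± 0.18) and the contractile proteins TAGLN (-0.81 ± 0.16) and ACTA2 (-0.77 ± 0.16). They were the 4 of 13 such markers that fell (5 fell and 1 rose adjusted over the list alone). For the smooth muscle list camera gave adjusted p = 4.3e-06, and adjusted p = 0.20 with an estimated correlation.

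**Figure D2:**
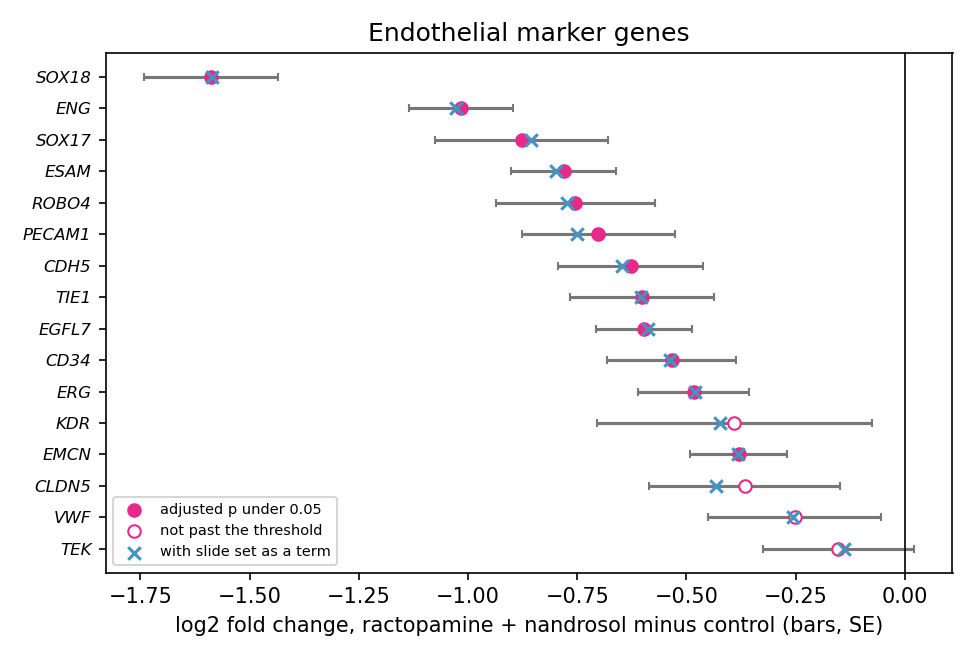
Log2 fold change (treated minus control, horizontal axis) with its SE for each of the 16 endothelial markers tested, ractopamine with nandrosol (8 arrays) against control (10 arrays). Filled points mark the 12 genes with an adjusted p under 0.05, all lower, from SOX18 (-1.59) upwards.

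Glucocorticoid-responsive and fat cell genes fell in the same muscle. The clock gene PER1, which glucocorticoids also induce, was 2.94-fold lower (-1.56 ± 0.23, adjusted p = 3.4e-05). PDK4, which restrains glucose oxidation, was lower by 3.46-fold (-1.79 ± 0.42, adjusted p = 0.0073), and FKBP5, a co-chaperone of the glucocorticoid receptor, 2.8-fold (-1.49 ± 0.32, adjusted p = 0.0032). With the transcription factor ZBTB16 (-1.04 ± 0.23) they were among 7 of 26 glucocorticoid targets that fell, with 0 that rose (10 fell adjusted over the list alone). For the glucocorticoid targets camera gave adjusted p = 4.3e-05, and adjusted p = 0.51 with an estimated correlation. FKBP5 gave -1.15 within slide set 1 and -3.01 within set 2. PER1 and CRY2 (-0.61 ± 0.15) were the 2 of 16 clock genes that fell (4 fell and 1 rose adjusted over the list alone). For the clock list camera gave adjusted p = 0.039, and adjusted p = 0.51 with an estimated correlation. Among fat cell genes, the lipid droplet protein CIDEC was 7.18-fold lower (-2.84 ± 0.77, adjusted p = 0.023), the fatty acid carrier FABP4 4.99-fold (-2.32 ± 0.69, adjusted p = 0.041). The adipocyte regulator PPARG was 2.01-fold lower (-1.01 ± 0.21, adjusted p = 0.0024). These were 3 of 15 adipocyte markers (5 fell and 2 rose adjusted over the list alone). For the adipocyte list camera gave adjusted p = 0.045 (0.053 with slide set as a term and 0.73 with an estimated correlation). The FABP4 call ended in 11 of 18 fits that each left out 1 array (highest adjusted p = 0.10, without ractopamine replicate 36), that of CIDEC in 3 (0.067, without replicate 37).

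CREM, a transcription factor that cAMP induces, was 2.47-fold lower (-1.30 ± 0.21, adjusted p = 1.4e-04). It was the 1 of 20 beta-adrenergic and cAMP genes that fell. That list and the hypoxia list, in which EGLN3 (-0.88 ± 0.18) and the vasodilator peptide gene ADM (-0.92 ± 0.20) were the 2 of 12 that fell, were lower. Camera gave them adjusted p = 0.035 and 0.041, and adjusted p = 0.53 and 0.51 with an estimated correlation. Extracellular matrix genes (2 of 35 fell, TIMP2 (-0.53 ± 0.12) and COL4A2 (-0.81 ± 0.24)), Schwann cell genes (2 of 10, NGFR (-0.83 ± 0.18) and PMP22 (-0.76 ± 0.21)) and macrophage genes (0 of 16, with CD163 at -0.72 ± 0.30, adjusted p = 0.17) were lower as lists. Their camera adjusted p was 9.1e-04, 0.0075 and 0.041, and adjusted p = 0.76, 0.51 and 0.90 with an estimated correlation. Adjusted over the list alone, 3, 2 and 0 members fell, and 1 and 4 of the cAMP and hypoxia lists, the latter with 1 that rose. Other large falls were in the acyl-CoA synthetase gene ACSM1 (-2.33 ± 0.60), the prion family gene PRND (-2.23 ± 0.59), and the transporters SLC16A6 (-2.00 ± 0.36) and SLC43A2 (-1.87 ± 0.29). The collagen hydroxylase gene P4HA3 fell as well (at least 2.99-fold lower, since it was near background in treated muscle).

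The largest rise was in GPX2, a glutathione peroxidase, 3.98-fold higher (1.99 ± 0.40, adjusted p = 0.0020). It was followed by the monocyte attractant CCL2 (1.47 ± 0.38, adjusted p = 0.018), ELAPOR2 (1.35 ± 0.40), C17H22orf31 (1.31 ± 0.34), and TCERG1L (1.08 ± 0.26). The potassium channel gene KCNJ2 (1.06 ± 0.22), the myogenic regulator MYOD1 (1.06 ± 0.32) and the ubiquitin ligase gene RNF122 (1.03 ± 0.31) rose as well, and all 7 lay above the control mean in at least 7 of 8 treated arrays. The call of CCL2 ended without ractopamine replicate 37 (adjusted p = 0.051), that of MYOD1 in 15 of 18 fits that left out 1 array (highest 0.099) and with slide set as a term (1.03 ± 0.32, 0.054). With normexp background correction ELAPOR2 (-0.10) and TCERG1L (-0.18) turned lower. The antioxidant genes SOD1 (0.59 ± 0.13), PRDX1 (0.34 ± 0.09) and TXN (0.36 ± 0.10) rose, although their list was not shifted (camera adjusted p = 0.72). Genes of the proteasome were slightly higher as a list (median 0.21 over 31 genes), with 1 call, PSMA5 (0.36 ± 0.10), and 9 adjusted over the list alone. For the proteasome list camera gave adjusted p = 6.1e-07, and adjusted p = 0.73 with an estimated correlation. Ribosomal protein genes were higher as a list by a median of 0.13 with 0 of 50 called (camera adjusted p = 0.0074; adjusted p = 0.96 with an estimated correlation), and RPL3 (-0.28 ± 0.10) leaned lower. Among the genes looked at in every comparison, FKBP5 and PDK4 fell and 11 did not pass. They were TSC22D3, KLF9, FBXO32, TRIM63, MSTN, IGF1, OXT (-0.40), NR3C1, ESR1 (0.43), MYH1 and MYH7, of which OXT and ESR1 lay at the ends of the range.

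In all, 330 probes were higher and 464 lower (234 and 391 gene symbols). With slide set as a term the counts were 348 and 489, with 773 probes called in both fits in the same direction, and within set 1 alone they were 294 and 379 (1 and 0 within set 2). They were 388 and 497 with scan day as a term, and within days 1, 2 and 3 they were 179 and 246, 0 and 23, and 0 and 0. The adipocyte list was the only list call that ended with scan day as a term (adjusted p = 0.075). Only 237 probes were called with normexp background correction and 434 when no other group was in the fit, and scaling by the array median moved the higher share from 41.6% to 28.5%. The calls of COL4A2, ELAPOR2, RNF122, PSMA5, PMP22, PRND and TXN ended in some fits that left out 1 array, with a highest adjusted p of 0.11 (without ractopamine replicate 39), 0.099 (36), 0.086 (without control replicate 9), 0.068 (ractopamine replicate 37), 0.067 (38), 0.064 (39) and 0.052 (37).

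With dexamethasone and estradiol, genes that glucocorticoids induce were far lower than in control muscle. PER1 was 13.7-fold lower (-3.78 ± 0.25, adjusted p = 9.3e-14, n = 6 and 10) and FKBP5 7.03-fold lower (-2.81 ± 0.34, adjusted p = 4.1e-07), and the differentiation factor CEBPD 4.22-fold (-2.08 ± 0.37, adjusted p = 1.5e-04). Among 26 glucocorticoid targets, 10 fell and 1 rose, the lipase inhibitor ANGPTL4, which was 14.7-fold higher (3.88 ± 0.66, adjusted p = 8.3e-05). Adjusted over the list alone the counts were 12 and 1. For the glucocorticoid targets camera gave adjusted p = 4.3e-06 (7.4e-09 with slide set as a term), and adjusted p = 0.51 with an estimated correlation. Within slide set 2 (5 treated and 2 control arrays) PER1 changed by -4.24 and FKBP5 by -4.01, and within set 1 (1 and 8) by -2.88 and -1.95. ANGPTL4 was higher by less within set 2 (1.88 ± 0.98) than within set 1 (3.69). The receptor gene itself, NR3C1 (-0.01 ± 0.17), and the targets TSC22D3 (-0.24 ± 0.24), KLF9 (-0.23 ± 0.16) and PDK4 (-0.72 ± 0.45) did not pass. Clock genes besides PER1 fell as well, PER3 (-1.99 ± 0.34), PER2 (-1.18 ± 0.27) and CRY2 (-0.63 ± 0.16), within 5 of 16 (the same count adjusted over the list alone; list median -0.04). For the clock list camera gave adjusted p = 0.042, and adjusted p = 0.51 with an estimated correlation. Macrophage markers moved down beside these genes: 7 of 16 fell, among them ITGB2 (-0.57 ± 0.14), LYZ (-1.01 ± 0.29), AIF1 (-0.84 ± 0.25) and LAPTM5 (-0.64 ± 0.19) (10 adjusted over the list alone). For the macrophage list camera gave adjusted p = 5.1e-04, and adjusted p = 0.73 with an estimated correlation.

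**Figure D3:**
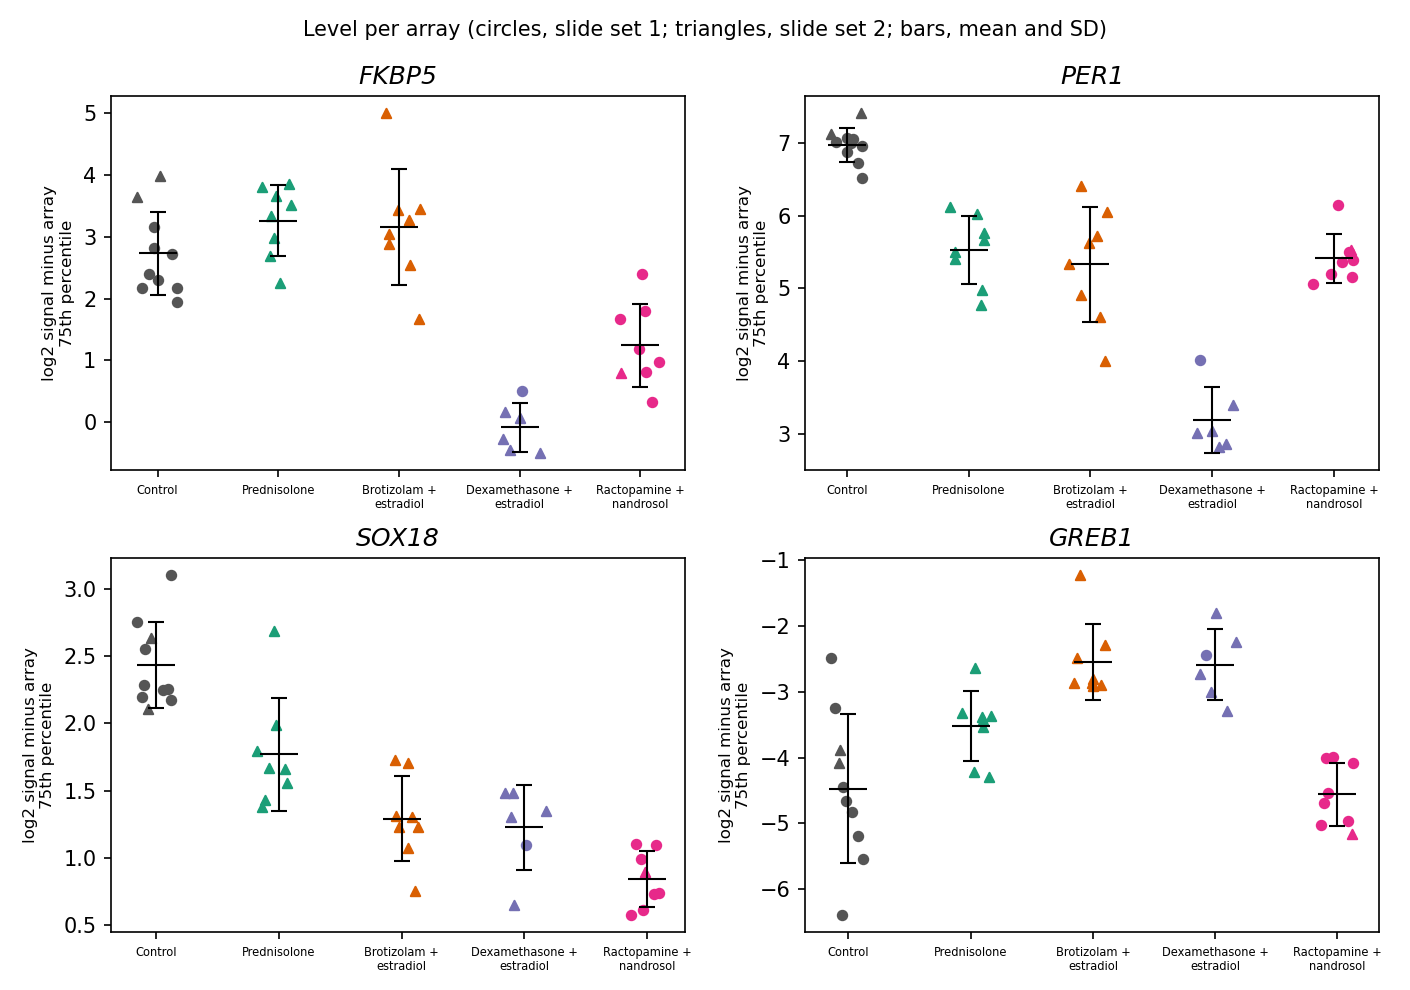
Level of FKBP5, PER1, SOX18 and GREB1 in each array (log2 signal minus the array's 75th percentile) by group, with the mean and SD as bars and the slide set as the point shape. Mean FKBP5 was 2.73 in control and -0.08 with dexamethasone and estradiol, and mean SOX18 was 2.43 in control and 0.84 with ractopamine and nandrosol.

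Genes induced within minutes of a stimulus were lower too. The nuclear receptor NR4A2 was 8.55-fold lower (-3.10 ± 0.44, adjusted p = 5.9e-06). With it, KLF4 (-1.95 ± 0.20), KLF6 (-1.76 ± 0.19), IER5 (-1.84 ± 0.35) and NR4A1 (-1.64 ± 0.28) were among 7 of 21 immediate early genes that fell, with 2 that rose (the same counts adjusted over the list alone). For the immediate early list camera gave adjusted p = 0.0018, and adjusted p = 0.73 with an estimated correlation. In the beta-adrenergic and cAMP list 7 of 20 fell and 2 rose, also adjusted over the list alone, including CREM (-1.39 ± 0.23) and FOSL2 (-2.01 ± 0.40). For the cAMP list camera gave adjusted p = 0.026, and adjusted p = 0.51 with an estimated correlation. The largest falls of all were in RGS1, a brake on G protein signalling (16.7-fold, -4.06 ± 0.38, adjusted p = 1.7e-09), PRND (-4.03 ± 0.65), and the Wnt inhibitor DKK1 (-3.86 ± 0.34). They were followed by the xenobiotic enzyme gene CYP1A1 (-3.35 ± 0.45), the transcriptional regulator ARID5B (-3.04 ± 0.33) and the Notch pathway gene HES6 (at least 7.86-fold lower, near background in treated muscle). Cell division genes fell from a low level: CCNB2 (at least 4.26-fold), CCNB1 (at least 3.37-fold), CCNA2 (at least 1.99-fold) and TOP2A (-1.96 ± 0.36) were among 9 of 25, while 2 rose (10 and 2 adjusted over the list alone). For the cell division list camera gave adjusted p = 0.017, and adjusted p = 0.73 with an estimated correlation.

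Rises were led, after ANGPTL4, by the guanylate-binding protein GBP5 (2.99 ± 0.77, adjusted p = 0.0064), the tryptophan-degrading enzyme IDO1 (2.83 ± 0.42, adjusted p = 1.0e-05), and ZNF475 (2.62 ± 0.65). The nuclear receptor ESRRG (2.59 ± 0.37, adjusted p = 6.5e-06), the AMP deaminase AMPD3 (2.29 ± 0.64), CCL2 (2.17 ± 0.42) and TMEM218 (2.09 ± 0.66) came next. Of these TMEM218 turned lower with slide set as a term (-0.51), and GBP5 missed the threshold there (2.78 ± 0.93, adjusted p = 0.066). AMPD3 (1.45 ± 0.75, adjusted p = 0.30) and ZNF475 (still higher, 0.13) missed it with scan day as a term. Genes of the interferon response rose, IFIT3 (1.89 ± 0.32), IRF1 (0.90 ± 0.22), IFI44 (1.12 ± 0.30) and RSAD2 (0.81 ± 0.18) among 6 of 21 (7 adjusted over the list alone), although with normexp background correction IFIT3, IFI44 and RSAD2 turned lower. For the interferon list camera gave adjusted p = 0.038, and adjusted p = 0.88 with an estimated correlation. Fatty acid oxidation genes rose, ACOT2 (1.65 ± 0.31), the fatty acid transporter CD36 (0.93 ± 0.17), ACADL (0.89 ± 0.20) and ACSL1 (0.76 ± 0.17) among 8 of 28 (9 adjusted over the list alone), although ACADL (-0.0088), like ZNF475 (-0.32), turned with normexp background correction. For the fatty acid list camera gave adjusted p = 0.0032, and adjusted p = 0.76 with an estimated correlation. In the insulin-like growth factor axis the receptor IGF1R (1.04 ± 0.16) rose while IGF2 (-0.79 ± 0.19) and the kinase subunit PIK3R1 (-0.85 ± 0.22) fell, and IGF1 (-0.03 ± 0.22) did not pass. The myogenic regulator MYOG (1.34 ± 0.30) rose while the fetal acetylcholine receptor subunit CHRNG (-2.19 ± 0.37), the fetal troponin TNNT2 (-1.61 ± 0.30) and the satellite cell cadherin CDH15 (-0.77 ± 0.13) fell. GREB1, an estrogen-induced gene, was 3.69-fold higher (1.89 ± 0.37, adjusted p = 4.4e-04; 1.84 with slide set as a term, adjusted p = 0.0093; above the control mean in 6 of 6 arrays), from a control level above background in 7 of 10 arrays.

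Endothelial and matrix genes were lower, while genes of smooth muscle and pericytes were not shifted (0 of 13 past the threshold, list median 0.06, camera adjusted p = 0.91). Endothelial markers fell in 7 of 16 cases, led by SOX18 (-1.20 ± 0.17, adjusted p = 3.5e-06), PECAM1 (-0.96 ± 0.19), ERG (-0.65 ± 0.14) and CDH5 (-0.72 ± 0.18) (10 adjusted over the list alone). For the endothelial list camera gave adjusted p = 1.5e-04, and adjusted p = 0.53 with an estimated correlation. Matrix genes fell in 10 of 35 cases, with COL5A3 (-1.10 ± 0.21), the collagen chaperone SERPINH1 (-0.76 ± 0.17), MMP2 (-0.68 ± 0.17) and COL15A1 (-0.80 ± 0.21) (12 adjusted over the list alone). For the matrix list camera gave adjusted p = 1.5e-04, and adjusted p = 0.73 with an estimated correlation. Cholesterol synthesis genes such as MVD (-0.68 ± 0.15) and MVK (-0.57 ± 0.15) fell in 5 of 20 cases and rose in 1 (5 and 2 adjusted over the list alone). For the cholesterol list camera gave adjusted p = 0.015 (0.15 with slide set as a term), and adjusted p = 0.80 with an estimated correlation. Ribosomal protein genes were lower as a list, with RPL3 (-0.43 ± 0.11) and RPL7 (-0.43 ± 0.12) among the 4 of 50 that fell (3 adjusted over the list alone). For the ribosomal list camera gave adjusted p = 0.0053, and adjusted p = 0.96 with an estimated correlation. The list was higher with normexp background correction (adjusted p = 0.0012).

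Among the genes looked at in every comparison, FKBP5, the ubiquitin ligase TRIM63 (-0.76 ± 0.25, adjusted p = 0.029) and the estrogen receptor ESR1 (-0.54 ± 0.18, adjusted p = 0.034) fell and OXT (0.82 ± 0.27, adjusted p = 0.032) rose. The last 3 missed the threshold with slide set as a term. TRIM63 kept its fold there (-0.91 ± 0.30, adjusted p = 0.055) and also missed it without dexamethasone replicate 28 (0.10). ESR1 was smaller (-0.40 ± 0.22, 0.32), and OXT was near 0 (0.12 ± 0.26, 0.87) and lower within slide set 2 (-0.30). Without dexamethasone replicate 30 the calls of ESR1 (0.10), OXT (0.087) and TMEM218 (0.071) ended, and without replicate 31 that of LAPTM5 (0.079). Besides the genes given above, MSTN (-0.97), FBXO32 (0.06), MYH1 (0.51) and MYH7 (0.28) did not pass, and MYH1 and MYH7 turned lower with slide set as a term (-0.10 and -0.24). In all, 1631 probes were higher and 1254 lower, and with slide set as a term 474 and 555, of which 928 were called in both fits in the same direction. With that term fewer list members fell than without it, 8 against 10 for glucocorticoid targets, 1 against 7 for macrophage, 3 against 10 for matrix, 2 against 7 for endothelial and 0 against 5 for cholesterol genes. The counts were 4 against 7 for immediate early, 5 against 7 for cAMP, 4 against 5 for clock, 6 against 9 for cell division and 2 against 4 for ribosomal genes, and of rises 5 against 8 for fatty acid oxidation and 3 against 6 for interferon response genes. Within slide set 2 the probe counts were 55 and 176, within set 1 49 and 52. They were 325 and 562 with scan day as a term, within day 2 72 and 267, and within day 3 21 and 33. The cholesterol list was the only list call that ended with scan day as a term (adjusted p = 0.11). The sum fell to 1823 without dexamethasone replicate 30, and scaling by the array median moved the higher share from 56.5% to 35.3%.

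With brotizolam and estradiol, GREB1 was 3.81-fold higher (1.93 ± 0.34, adjusted p = 8.0e-05, n = 8 and 10, in 8 of 8 arrays above the control mean). The change was 1.87 with slide set as a term (adjusted p = 0.015), 1.43 within slide set 2 and -0.0068 with normexp background correction. The control level of GREB1 was above background in 7 of 10 arrays. The clock gene PER1 was 3.12-fold lower (-1.64 ± 0.23, adjusted p = 2.7e-06; within set 2 -1.93). NR4A2 was 10.7-fold lower (-3.42 ± 0.41, adjusted p = 2.7e-07; within set 2 -2.88), the lymphoid regulator RUNX3 10.9-fold (-3.44 ± 0.39, adjusted p = 1.2e-07; within set 2 -2.16). SOX18 was 2.2-fold lower (-1.14 ± 0.15, adjusted p = 2.0e-06; within set 2 -1.08). All 4 falls passed with slide set as a term (adjusted p = 0.0022, 3.5e-04, 0.0029 and 0.0014). With scan day as a term, where this group shares no day with a control, RUNX3 (-0.22 ± 0.59, adjusted p = 0.95), SOX18 (-0.91 ± 0.33, 0.26) and NR4A2 (-3.02 ± 0.86, 0.13) no longer passed while PER1 did (0.038).

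Further large falls that passed with slide set as a term were in the adaptor DOK3 (-2.76 ± 0.28), RAPH1 (-2.41 ± 0.27), the mitochondrial gene COQ10B (-2.33 ± 0.29) and the elongation factor ELL2 (-2.09 ± 0.24), each below the control mean in 8 of 8 arrays. The growth inhibitor myostatin (MSTN, -2.13 ± 0.41, adjusted p = 2.6e-04) missed it there with a similar fold and a larger SE (-1.80 ± 0.56, adjusted p = 0.056; -2.21 within slide set 2), and with scan day as a term it was 0.30 ± 0.77. The fall of VWA1 (at least 2.7-fold lower) shrank with slide set as a term (-0.84 ± 0.46, adjusted p = 0.33). The 8 largest rises, C14H8orf34 (3.71), TMEM218 (3.59), LHX2 (3.22), ANGPTL4 (3.16), DIS3L2 (3.04), BAIAP2L2 (2.94), ZC3H4 (2.88) and MYO15A (2.67), had an SE of at most 0.61. None passed with slide set as a term, where they ranged from -0.28 (ZC3H4) to 1.76 (ANGPTL4). Genes that kept their call with that term included the adipogenic factor CEBPA (-1.62 ± 0.21, adjusted p = 9.4e-07), the macrophage growth factor CSF1 (-1.52 ± 0.21), the sodium channel SCN4A (-1.70 ± 0.21), the transcription factors KLF4 (-1.28 ± 0.19) and KLF6 (-0.59 ± 0.18), and the signal transducer STAT5A (-0.48 ± 0.11). Rises that kept it were in CCL2 (1.37 ± 0.38), the chaperones CRELD2 (0.91 ± 0.15) and CRYAB (0.93 ± 0.19), and the tropomyosin TPM3 (0.74 ± 0.20). With slide as a fixed term, where no slide held both groups, CSF1 (0.070) and SCN4A (0.21) turned higher. The receptor gene NR3C1 (-0.51 ± 0.15, adjusted p = 0.014) fell and OXT (1.19 ± 0.25, adjusted p = 6.7e-04) rose in the fit of groups only (with slide set as a term -0.60 ± 0.21, adjusted p = 0.091, and 0.31 ± 0.27, 0.58). By contrast, FKBP5 (0.43), TSC22D3 (-0.46), KLF9 (0.31), PDK4 (0.35), FBXO32 (-0.65), TRIM63 (-0.26), IGF1 (0.23) and ESR1 (-0.07) did not pass. The direction turned within slide set 2 for FKBP5 (-0.65), PDK4 (-0.63) and ESR1 (0.11).

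Among gene lists, cholesterol synthesis was lower (6 of 20 fell, led by DHCR7 (-0.66 ± 0.13) and SREBF2 (-0.61 ± 0.15), and 8 adjusted over the list alone). Endothelial markers were lower too (6 of 16 fell and 1, TEK (0.80 ± 0.17), rose; 9 and 1 adjusted over the list alone), and so were clock genes (4 of 16 fell, with NR1D2 (-0.85 ± 0.21) and BHLHE41 (-0.50 ± 0.14), and 1, RORA (0.65 ± 0.20), rose; the same counts adjusted over the list alone). Heat shock and unfolded protein genes were higher (9 of 33 rose and 1, DNAJB1 (-1.28 ± 0.33), fell; 11 and 2 adjusted over the list alone). Camera gave these 4 lists adjusted p = 7.9e-04, 0.0024, 0.020 and 0.050, with slide set as a term 0.044, 0.044, 0.020 and 0.012. Most calls of single members ended with that term, which left 0, 1 and 2 that fell and 2 that rose. With an estimated correlation the 4 lists had adjusted p = 0.73, 0.73, 0.51 and 0.88. With scan day as a term only cholesterol synthesis kept its call (0.045), while clock genes (0.075), heat shock genes (0.052) and endothelial markers (0.67, list median 0.016) did not. Lists called only with scan day as a term were glucocorticoid targets (0.025), macrophage (6.3e-04), cAMP (0.046) and immediate early genes (0.040), all lower, and interferon response genes, higher (0.019). None of these 5 passed with an estimated correlation (adjusted p = 0.79, 0.79, 0.69, 0.92 and 0.92). Without slide set in the fit, muscle fibre, energy and ribosomal lists were called higher, and all lost the call with that term. This held for fast fibre genes (8 of 12 rose, with MYH1 (0.98 ± 0.19); adjusted p = 0.0018, with the term 0.61) and slow fibre genes (5 of 12, with MYH7 (0.78 ± 0.17) and MYL2 (1.04 ± 0.17); 0.0026, 0.069). It also held for oxidative phosphorylation (9 of 58, with ATP5PO (0.48 ± 0.11), while 1 fell; 0.0097, 0.20) and ribosomal proteins (13 of 50, with RPL34 (1.20 ± 0.19), while 1 fell; 0.015, 0.34). The last such lists were glycolysis (8 of 23, with ALDOA (0.75 ± 0.14); 0.021, 0.91 and lower) and fatty acid oxidation (4 of 28, with PPARA (0.99 ± 0.27); 0.026, 0.16). With slide set as a term, all of these lists except glycolysis kept a positive median, from 0.047 (oxidative phosphorylation) to 0.23 (slow fibre). With an estimated correlation these 6 lists gave adjusted p = 0.73, 0.73, 0.96, 0.96, 0.94 and 0.88. Of these, only the ribosomal list kept its call with scan day as a term (0.040). Quantile normalization turned the ribosomal and glycolysis lists lower (adjusted p = 0.87 and 0.99). Adjusted over the list alone, 8, 6, 7, 16, 9 and 4 of their members rose, and 1 oxidative phosphorylation and 1 ribosomal gene fell.

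In all, 1787 probes were higher and 1510 lower (1864 and 7974 with normexp background correction, 1989 and 5060 with no filter on dim probes), and with slide set as a term 289 and 380, of which 548 were called in both fits in the same direction. Within slide set 2, against 2 controls, 55 were higher and 95 lower, and 62 passed in either direction with scan day as a term. The call of RORA ended without brotizolam replicate 19 (adjusted p = 0.053).

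With prednisolone, few changes could be told apart from the slide set. NR4A2 was 7.88-fold lower (-2.98 ± 0.41, adjusted p = 1.3e-05, n = 8 and 10; -3.16 with slide set as a term, adjusted p = 0.0039). PER1 was 2.72-fold lower (-1.45 ± 0.23, adjusted p = 6.5e-05; -1.41, 0.028) and the transcription factor KLF4 2.66-fold lower (-1.41 ± 0.19, adjusted p = 8.6e-06; -1.32, 0.0091). CCL2 was 4.07-fold higher (2.02 ± 0.38, adjusted p = 4.1e-04; 2.40, 0.027). Each moved that way in 8 of 8 treated arrays, and within slide set 2 they gave -2.44, -1.74, -1.29 and 3.03. None of the 4 passed with scan day as a term (adjusted p from 0.056 to 0.20), where the folds stayed of like size (-2.66 ± 0.69, -1.71 ± 0.39, -1.19 ± 0.32 and 2.25 ± 0.62) and the SE grew. The 8 largest rises, TMEM218 (3.64), ZC3H4 (3.60), C14H8orf34 (3.57), ANGPTL4 (3.51), LHX2 (3.36), NRTN (3.04), BAIAP2L2 (3.00) and DIS3L2 (2.85), had an SE of at most 0.61. All missed the threshold with slide set as a term (smallest log2 fold change 0.25 for BAIAP2L2, lowest adjusted p = 0.24 for ANGPTL4). So did the falls of PRND (-2.75 ± 0.59), RUNX3 (-2.22 ± 0.39), FAM3B (-2.10 ± 0.43), INTS9 (-2.00 ± 0.62), myostatin (MSTN, -2.00 ± 0.41), FOS (-1.91 ± 0.45) and VWA1 (at least 2.37-fold lower). Their adjusted p there ran from 0.17 (FAM3B) to 0.58 (VWA1). With that term PRND (-2.45 ± 0.82), FAM3B (-1.84 ± 0.60), INTS9 (-2.45 ± 0.85), MSTN (-1.68 ± 0.56) and FOS (-1.52 ± 0.61) kept most of their fold with a larger SE, while RUNX3 (-0.71 ± 0.39) and VWA1 (-0.73 ± 0.46) shrank. MSTN was -2.08 within slide set 2 and -1.92 within day 3, but -0.39 ± 0.61 with scan day as a term. INTS9 also lost its call without prednisolone replicate 18 (adjusted p = 0.054).

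Endothelial markers were lower, 9 of 16 with 0 that rose (10 and 1 adjusted over the list alone), among them ESAM (-0.66 ± 0.12), the tight junction gene CLDN5 (-1.19 ± 0.22), SOX18 (-0.66 ± 0.15) and PECAM1 (-0.69 ± 0.18). PECAM1 turned higher with scan day (0.10) or slide (0.13) as a fixed term. For the endothelial list camera gave adjusted p = 1.9e-05 (2.4e-04 with slide set as a term, where 0 members passed singly), and adjusted p = 0.51 with an estimated correlation. Cholesterol synthesis genes were lower (5 of 20 fell, with SQLE (-1.31 ± 0.32) and SREBF2 (-0.56 ± 0.15), also adjusted over the list alone). For the cholesterol list camera gave adjusted p = 5.9e-04 (0.020 with the term, where 0 members passed), and adjusted p = 0.73 with an estimated correlation. Immediate early genes were lower too (7 of 21 fell and 2 rose, also adjusted over the list alone, with NR4A1 (-1.37 ± 0.26) and ZFP36 (-0.98 ± 0.20)). For their list camera gave adjusted p = 0.021 (0.015 with the term, where 1 fell), and adjusted p = 0.82 with an estimated correlation. Ribosomal protein genes rose in 24 of 50 cases (26 adjusted over the list alone), with RPL34 (1.04 ± 0.19) and RPS7 (0.56 ± 0.10), by a list median of 0.26. For the ribosomal list camera gave adjusted p = 1.4e-06, and adjusted p = 0.76 with an estimated correlation. With slide set as a term the list kept its call (8.6e-05) with 0 members called. In the fit of groups only, fast fibre (7 of 12 rose, with MYH1 (0.81 ± 0.19); turned lower with slide set as a term, adjusted p = 0.76) and slow fibre genes (5 of 12, with MYH7 (0.70 ± 0.17); 0.17 with the term) were higher. So were genes of oxidative phosphorylation (9 of 58, with UQCRC2 (0.61 ± 0.13); 0.087 with the term, and lower with quantile normalization, 0.97) and fatty acid oxidation (3 of 28, with PPARGC1A (2.37 ± 0.44); 0.14). Camera gave these 4 adjusted p = 0.0091, 0.0082, 0.0039 and 0.032, and adjusted p = 0.76, 0.76, 0.96 and 0.90 with an estimated correlation. Adjusted over the list alone, 8, 6, 8 and 3 members rose. With scan day as a term these 4 lists lost their calls (lowest adjusted p = 0.34), while the endothelial (0.015), cholesterol (0.028), immediate early (9.2e-04) and ribosomal (0.0024) lists kept theirs. Their medians there were -0.13, -0.18, -0.58 and 0.14, against -0.46, -0.27, -0.25 and 0.26 in the fit of groups only. Within day 3 alone (4 treated arrays and 1 control) they were -0.11, 0.16, 0.06 and 0.03, so the cholesterol and immediate early lists turned. Lists called only with slide set as a term were glycolysis, lower (0.012), and heat shock (0.013) and antioxidant genes (0.047), higher, and all lost the call with an estimated correlation (adjusted p = 0.93, 0.86 and 0.86). Only with scan day as a term, macrophage (1.0e-04) and cAMP genes (0.021) were lower and interferon response genes (0.025) higher, again not with an estimated correlation (adjusted p = 0.69, 0.68 and 0.92).

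FKBP5 did not pass with prednisolone (0.53 ± 0.32, adjusted p = 0.25), nor did TSC22D3 (-0.29), KLF9 (0.20), PDK4 (0.11), FBXO32 (0.01), TRIM63 (0.20), IGF1 (-0.16), NR3C1 (-0.00027) or ESR1 (0.35). The direction turned within slide set 2 for FKBP5 (-0.55), PDK4 (-0.87), TRIM63 (-0.13) and NR3C1 (0.18). The list of glucocorticoid targets did not pass camera in the fit of groups only (median 0.01, mean 0.08, camera direction lower, adjusted p = 0.64; with slide set as a term median -0.25, adjusted p = 0.041). It was lower with scan day as a term (median -0.28, adjusted p = 0.0030). With an estimated correlation adjusted p was 0.96, 0.93 and 0.69 in the 3 fits. OXT rose (0.92 ± 0.25, adjusted p = 0.0087) in the fit of groups only, did not pass with slide set as a term (0.04 ± 0.27, adjusted p = 0.98) and was lower within slide set 2 (-0.25). GREB1, singled out after its values were seen, rose by 0.95 ± 0.34, adjusted p = 0.044. This call ended with slide set as a term (0.89 ± 0.46, adjusted p = 0.47), with normexp background correction (-0.16) and in 12 of 18 fits that left out 1 array (highest 0.10, without prednisolone replicate 17). In all, 1787 probes were higher and 1104 lower, and with slide set as a term 23 and 49, of which 68 were called in both fits in the same direction. Within slide set 2, against 2 controls, 4 were higher and 19 lower, and 22 passed in either direction with scan day as a term (3 and 1 within day 3).

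**Figure D4:**
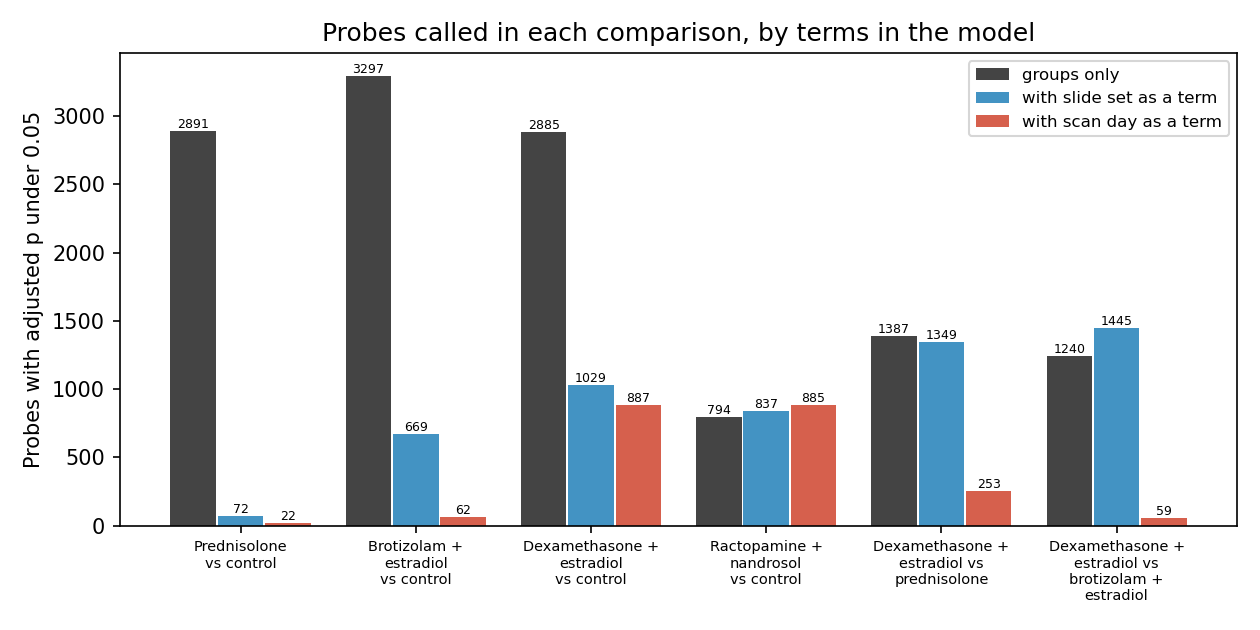
Number of probes with an adjusted p under 0.05 (vertical axis, of 16110 tested) in each of the 6 comparisons, with groups only, with slide set as a term or with scan day as a term. For prednisolone against control the bars stand at 2891, 72 and 22, and for ractopamine with nandrosol at 794, 837 and 885.

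Dexamethasone with estradiol and prednisolone were compared directly, as regimens with a glucocorticoid at different doses and with or without estradiol. FKBP5 was 10.2-fold lower with dexamethasone and estradiol (-3.34 ± 0.36, adjusted p = 2.2e-07, n = 6 and 8; -3.29 with slide set as a term, -3.46 with scan day as a term). The collagen hydroxylase P4HA3 was 8.36-fold lower (-3.06 ± 0.48, adjusted p = 9.7e-05), and SYT4 (-2.86 ± 0.78), the centromere gene CENPA (-2.72 ± 0.42) and the DNA methylation gene UHRF1 (-2.67 ± 0.43) were lower. IDO1 was 7.6-fold higher (2.93 ± 0.44, adjusted p = 5.5e-05), with SOS1 (at least 3.16-fold), BCL2L14 (1.89 ± 0.58), the chemokine CCL8 (1.73 ± 0.54) and THADA (1.73 ± 0.22). Every fall held in 6 of 6 dexamethasone arrays and the rises in at least 5 of 6. With normexp background correction SOS1 (-0.077), BCL2L14 (-0.16) and THADA (-0.13) turned lower. The calls of BCL2L14 and CCL8 ended in 8 and 7 of 14 fits that left out 1 array (highest adjusted p = 0.11 without dexamethasone replicate 29 and 0.10 without replicate 30). GREB1 did not differ past the threshold (0.93 ± 0.38, adjusted p = 0.12). In all 692 probes were higher and 695 lower, 1349 in either direction with slide set as a term and 253 with scan day as a term, and within slide set 2 433 and 536 (39 and 67 within day 3). The count fell from 1387 to 815 without dexamethasone replicate 31 and to 814 with only these groups in the fit, and the array median moved the higher share from 49.9% to 35.6%.

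Against brotizolam with estradiol, dexamethasone with the same estradiol schedule gave lower FKBP5 (9.46-fold, -3.24 ± 0.36, adjusted p = 4.5e-07, n = 6 and 8; -3.19 with slide set as a term). RGS1 (8.96-fold, -3.16 ± 0.40, adjusted p = 4.3e-06), P4HA3 (-2.98 ± 0.48), CYP1A1 (-2.62 ± 0.47) and PRND (-2.60 ± 0.68) were lower too, each in 6 of 6 arrays. The largest rises were in GBP5 (2.95 ± 0.80), IDO1 (2.66 ± 0.44), GBP1 (2.31 ± 0.54), the nuclease gene ISG20 (at least 3.16-fold) and RUNX3 (2.05 ± 0.44), of which RUNX3 turned lower with scan day as a term (-0.62). The call of GBP5 ended without dexamethasone replicate 31 (adjusted p = 0.059). GREB1 did not differ (-0.04 ± 0.38, adjusted p = 0.96). In all 643 probes were higher and 597 lower, 1445 in either direction with slide set as a term and 59 with scan day as a term, and within slide set 2 432 and 455. No scan day held both groups. Without dexamethasone replicate 31 the count fell from 1240 to 753, and the array median moved the higher share from 51.9% to 32.2%.

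Across the 5 groups, 7008 probes (43.5%) differed by a moderated F-test, 3034 with slide set as a term and 1787 with scan day as a term. The largest rises among them were in ANGPTL4 (adjusted p = 1.7e-07), C14H8orf34 (adjusted p = 1.2e-06), TMEM218 (adjusted p = 1.0e-06), ZC3H4 (adjusted p = 2.8e-06) and LHX2 (adjusted p = 1.9e-06). The largest falls were in RGS1 (adjusted p = 3.6e-09), PRND (adjusted p = 6.5e-05), DKK1 (adjusted p = 8.3e-10), PER1 (adjusted p = 5.3e-12) and RUNX3 (adjusted p = 2.1e-08). With slide set as a term C14H8orf34 (0.15) and ZC3H4 (0.069) missed the threshold. With scan day as a term C14H8orf34 (0.57), TMEM218 (0.44), ZC3H4 (0.23), LHX2 (0.78) and RUNX3 (0.23) missed it. PER1 was lower in all 4 treated groups. The largest overlap of calls was between prednisolone and brotizolam with estradiol, 1718 probes in the same direction (1077 higher and 641 lower), where independent lists would share 198.2 and 103.5. Groups simulated without any effect against shared controls gave 0. Noise alone yields hardly any calls, so this value cannot show what shared controls add to an overlap of many calls. Controls split into 5 and 5 gave 760, with fewer controls in each comparison. With slide set as a term that overlap was 58. Dexamethasone shared 1047 with prednisolone (338 with split controls, 51 with slide set as a term), 1247 with brotizolam (489.5 and 246) and 284 with ractopamine (86.5 and 196). Independent lists would share 180.9 higher and 85.9 lower, 180.9 and 117.5, and 33.4 and 36.1. Ractopamine shared 149 with prednisolone (37.5 and 21) and 127 with brotizolam (38 and 54), against 36.6 and 31.8, and 36.6 and 43.5. The simulation held no slide set effect, so the covariance of log2 fold changes minus the simulated value, which shared controls alone bring to 0, includes any difference between slide sets. It was 0.145 for prednisolone with brotizolam, 0.116 for prednisolone with dexamethasone, 0.119 for brotizolam with dexamethasone, 0.026 for dexamethasone with ractopamine, -0.0049 for prednisolone with ractopamine and -0.013 for brotizolam with ractopamine.

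The remaining 14 of 36 gene lists passed camera in no comparison in the fit of groups only. Their smallest adjusted p was 0.054 for fibroblast markers, 0.17 for antigen presentation, 0.20 for myogenesis and 0.23 for erythroid markers (ractopamine), 0.11 for lipid synthesis and 0.30 for estrogen response genes (prednisolone). It was 0.30 for atrophy and autophagy, 0.42 for the growth hormone and insulin-like growth factor axis and 0.51 for cytokines (brotizolam), 0.35 for lymphocyte markers and 0.36 for the citric acid cycle (ractopamine). For androgen and polyamine genes it was 0.67 and for antioxidant and metallothionein genes 0.69, and for genes of the denervated neuromuscular junction 0.75. Of these, lymphocyte markers were lower with dexamethasone and estradiol with slide set (adjusted p = 0.013) or scan day as a term (0.019), and fibroblast markers with ractopamine with slide set as a term (0.044). With an estimated correlation neither passed (adjusted p = 0.82, 0.76 and 0.94). Single members still changed in lists that were not shifted, such as the autophagy kinase ULK1 (0.72 ± 0.14) and the atrophy factor FOXO3 (-0.67 ± 0.17) with dexamethasone and estradiol.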

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

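The tests of glucocorticoid targets with dexamethasone, of the fibre share and of slide set 1 for the endothelial genes, and the counts over other splits of the arrays were chosen only after the result was seen. Of 75 checks of a group for an array far from the others (15 measures in 5 groups), 4 found one, and chance gives about 1 in 20. The 75th percentile of the processed signal was 1385 on brotizolam replicate 23, with the nearest array of its group at 1115 and the lowest at 872.7. The log2 level of TSC22D3 was -6.6354 in ractopamine replicate 35 (nearest -5.76), that of FBXO32 was 4.319 in control replicate 9 (nearest 5.25) and that of MYH7 was 7.9916 in brotizolam replicate 19 (nearest 8.63). No explanation for these arrays was tested.

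Prednisolone called 2891 probes against control and brotizolam with estradiol 3297, most of which were lost with slide set as a term (72 and 669 called). Over the probes called without the term, folds with it had a slope of 0.45 and 0.56 on those without it. The median SE over all probes rose from 0.174 to 0.228 in both comparisons. Smaller folds and a larger SE thus both enter the lower counts. If slide set were the cause, the called changes would follow the difference between slide sets measured on dexamethasone and ractopamine arrays, which enter neither comparison. That difference rests on 1 dexamethasone array in set 1 (5 in set 2) and 1 ractopamine array in set 2 (7 in set 1). Across the called probes the correlation with that difference was 0.692 for prednisolone and 0.628 for brotizolam with estradiol, with the same sign in 79.7% and 69.8% (genes are not independent replicates), so slide set is a candidate explanation for much of both counts. Calls did not gather among probes near the background: the share called among probes above background on all 40 arrays was 1.03 and 1.29 times that among the others. The counts still depended on how background was treated, with 722 and 9838 called after normexp background correction. A treatment effect on the same genes stays open for what slide set leaves, since only 2 controls share a slide set with these groups and no control was scanned on the day of the brotizolam arrays.

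With dexamethasone and estradiol, 10 glucocorticoid targets fell by a median of -1.07. Values with slide set as a term argue against the slide set as its cause. The median of the same genes, picked for their fall without the term, was -1.17 with it. Over all 26 targets tested the median was -0.65 without the term and -0.74 with it. The fit with the term rests on 1 dexamethasone array in set 1 and 2 controls in set 2. Another time of day at sampling stays open. The median of the clock genes NR1D2, DBP, TEF, HLF and BHLHE41 was 0.058 (from -0.53 to 0.29), but TEF fell (-0.53, adjusted p = 0.014), as did PER2, PER3 and CRY2. Fewer cells of other types in the sample stay open too, as macrophage markers had a median of -0.60, the lowest of 7 cell type lists, and several targets are also expressed in such cells. A biological candidate explanation is lower glucocorticoid receptor activity in the sampled muscle, but no hormone level was measured and this was not tested.

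With ractopamine and nandrosol, endothelial markers had a median of -0.60. If a larger share of fibre RNA lowered all other cell types alike, the endothelial median would match that of non-vascular markers. It lay -0.415 from that of 72 such markers (their median -0.184, exact test over the 19305 splits of the arrays within slide sets, two-sided, p = 0.0171). The endothelial list was picked on these same arrays for its strong call, which this p does not allow for. The gap therefore cannot decide on a larger share of fibre RNA. Neither ractopamine replicate 36, the array with the fewest probes above background, nor the slide set explains the low endothelial median: without that array it was -0.551, and within slide set 1 it was -0.607. A larger share of fibre RNA stays open, since the markers of non-vascular cells were lower too (list medians from -0.08 for lymphocytes to -0.29 for Schwann cells). Endothelial markers were also lower against the same controls with prednisolone (list median -0.46), brotizolam and estradiol (-0.35) and dexamethasone and estradiol (-0.43). With scan day as a term these medians were -0.13, 0.016 and -0.31. A difference on the control side therefore stays open too, since every comparison used these controls. Fewer vessels per fibre, or lower transcription in vessel cells, may underlie the rest, a hypothesis found on these arrays and not itself tested.

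For every count of called probes, no other of the 100 splits of the arrays gave as many as the real one. These splits moved arrays freely between slide sets, which the real groups share unevenly. They therefore cannot set a treatment effect apart from slide set. The real counts and the highest of the other splits were 2891 and 80 for prednisolone, 3297 and 3 for brotizolam with estradiol, 2885 and 1499 for dexamethasone with estradiol, 794 and 51 for ractopamine with nandrosol, 1387 and 342 for dexamethasone against prednisolone, 1240 and 159 for dexamethasone against brotizolam, and 7008 and 1 for the F-test. The split that gave 1499 correlated with slide set (0.618), and with slide set as a term the real count was 1029. With that term and splits within slide sets, the real split again gave the most: 72 against 17 at most (45 splits), 669 against 11 (45 splits), 1029 against 485, 837 against 282, 1349 against 66 and 1445 against 3, in the same order of comparisons. The F-test was not counted in this way.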

How the results depend on the processing

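The terms for slide set, for lists also scan day, were chosen only after the data were seen. Of 208 calls of named genes, where a gene counts once in each comparison that called it, quantile normalization kept 201 and the array median 201. The authors' values kept 198 and eBayes with trend and robust 208. Slide as a random block kept 204, slide set as a term 132, scan day as a term 104 and slide as a fixed term 88. The direction of the others was kept unless given here. Normexp background correction kept 136, and with it the median log2 fold change of all probes, which lay between 0.016 and 0.073 without it, was -0.21 for prednisolone, -0.42 for brotizolam, -0.35 for dexamethasone and -0.17 for ractopamine against control, -0.21 for dexamethasone against prednisolone and 0.14 against brotizolam. For every change below, the cause was not tested unless the fewer arrays or groups of the alternative give it. Scan day and slide as terms left brotizolam arrays without a control on the same day, and signal over background limits the genes given with "at least".

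Counts of called probes moved by more than 1.5 times as follows. Prednisolone (2891) gave 722 with normexp background correction, 4418 with array weights, 1767 with slide as a random block, 7 with slide as a fixed term, 22 with scan day, 72 with slide set, and 48 and 30 with slide set but without control replicate 9 or 10. Brotizolam with estradiol (3297) gave 9838 with normexp, 7049 with no filter, 4965 with array weights, 2197 with slide as a random block, 40 with slide, 62 with scan day, 669 with slide set, and 601 and 292 without those controls. Dexamethasone with estradiol (2885) gave 1467 with normexp, 5198 with array weights, 831 with slide, 887 with scan day, 1029 with slide set, and 814 and 724 without those controls. Ractopamine with nandrosol (794) gave 237 with normexp and 434 with only the compared groups. Dexamethasone against prednisolone (1387) gave 316 with normexp, 2411 with array weights, 307 with slide, 253 with scan day and 814 with only the compared groups. Dexamethasone against brotizolam (1240) gave 242 with normexp, 2821 with array weights, 642 with slide as a random block, 59 with slide and 59 with scan day. The F-test (7008) gave 1564 with slide, 1787 with scan day and 3034 with slide set. Overlaps moved with split controls to 760, 338, 37.5, 489.5, 38 and 86.5, and with slide set to 58, 51, 21, 246 and 54 (pairs in the order prednisolone with brotizolam, dexamethasone and ractopamine, brotizolam with dexamethasone and ractopamine, dexamethasone with ractopamine, the last moving with split controls only).

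Leaving out 1 array gave 2332 to 3510 probes for prednisolone, 2883 to 3786 for brotizolam, 1823 (without dexamethasone replicate 30) to 3627 for dexamethasone, 580 to 897 for ractopamine, 815 (without dexamethasone replicate 31) to 1709 for dexamethasone against prednisolone, 753 (without the same array) to 1442 against brotizolam and 6456 to 7390 for the F-test. It ended 22 of the 208 calls of named genes.

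Of 42 list calls, 1 was left with an estimated correlation. Quantile normalization gave 21 calls and the authors' values 24, and fry kept 27, slide set 30 and scan day 28. Normexp background correction kept 26 and called 17 further lists in an unchanged direction. Lists turned with quantile normalization: oxidative phosphorylation in prednisolone (adjusted p = 0.97) and ribosomal proteins (0.87) and glycolysis (0.99) in brotizolam. With normexp: antioxidants in brotizolam (0.013) and dexamethasone (0.0088), and ribosomal proteins (0.0012) and oxidative phosphorylation (6.3e-08) in dexamethasone. With slide set: fast fibre (0.76) and glycolysis (0.012) in prednisolone and glycolysis in brotizolam (0.91). With scan day: fatty acid oxidation in prednisolone (0.92).

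Single genes turned as follows (log2 fold changes). With normexp background correction: GREB1 (-0.16) in prednisolone, PPARA (-0.73), GREB1 (-0.0068) in brotizolam, ZNF475 (-0.32), ACADL (-0.0088), IFIT3 (-0.39), RSAD2 (-0.30), IFI44 (-0.68) in dexamethasone, ELAPOR2 (-0.10), TCERG1L (-0.18) in ractopamine, SOS1 (-0.077), BCL2L14 (-0.16), THADA (-0.13) in dexamethasone against prednisolone. With slide set as a term: ZC3H4 (-0.28) in brotizolam, TMEM218 (-0.51) in dexamethasone. With scan day as a term: C14H8orf34 (-0.071), PECAM1 (0.10) in prednisolone, C14H8orf34 (-0.54), TMEM218 (-0.043), BAIAP2L2 (-0.20), ZC3H4 (-0.47), MSTN (0.30) in brotizolam, RUNX3 (-0.62) in dexamethasone against brotizolam. With slide as a fixed term: TMEM218 (-0.14), ZC3H4 (-0.11), C14H8orf34 (-0.49), NRTN (-0.11), BAIAP2L2 (-0.24), RUNX3 (0.15), MYH7 (-0.015), MYH1 (-0.024), PECAM1 (0.13) in prednisolone, C14H8orf34 (-0.55), TMEM218 (-0.28), BAIAP2L2 (-0.43), ZC3H4 (-0.55), RUNX3 (0.17), MSTN (0.30), MYH7 (-0.15), MYH1 (-0.084), CSF1 (0.070), SCN4A (0.21) in brotizolam, TMEM218 (-0.44), OXT (-0.030) in dexamethasone, RUNX3 (-0.48) in dexamethasone against brotizolam.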

Other observations

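The estrogen-induced gene GREB1 was singled out after its values were seen, as a marker of the estradiol that both the brotizolam and the dexamethasone group received. Its mean log2 level was -2.55 with brotizolam and estradiol (SD 0.58, 8 arrays) and -2.59 with dexamethasone and estradiol (SD 0.54, 6 arrays), against -4.47 in control (SD 1.13, 10 arrays), -3.52 with prednisolone (SD 0.53, 8 arrays) and -4.56 with ractopamine and nandrosol (SD 0.48, 8 arrays). The direct comparison of dexamethasone and estradiol with prednisolone did not pass (0.93 ± 0.38, adjusted p = 0.12), and brotizolam with estradiol was not compared with prednisolone. Its own list of estrogen response genes was not shifted by camera in any comparison, with 3 of 16 that rose with brotizolam, 2 that rose and 1 that fell with dexamethasone, and 4 that rose and 1 that fell with prednisolone, which came without estradiol. By fry, the list passed in all 3 (adjusted p = 0.039, 0.019 and 0.0026), so it does not set the estradiol groups apart. Within slide set 2, against 2 controls, the log2 fold change of GREB1 was 1.43 with brotizolam and estradiol, 1.36 with dexamethasone and estradiol and 0.45 with prednisolone.

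TMEM218, among the largest rises with prednisolone and brotizolam, had a mean of 0.92 in control with an SD of 1.84. The 8 controls of slide set 1 ran from -0.86 to 0.89, while the 2 of set 2 lay at 4.34 and 4.10, within the range of the prednisolone arrays (4.03 to 5.22). Ractopamine replicate 38, the only one of its group in set 2, lay at 4.21. Dexamethasone replicate 31, the only one of its group in set 1, lay at -0.20. The level of TMEM218 thus followed slide set in the groups that held both sets. PER1 lay between 6.52 and 7.40 in the 10 control arrays and between 2.82 and 6.40 in all 30 treated arrays, so that no treated array reached the lowest control. The 4 treatments were all set against the same controls. A difference on the control side, such as in time of day at sampling, therefore cannot be told apart from effects of the treatments.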
